A study of Mus musculus with 6 samples.

How the data were processed

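RNA was measured in 6 libraries of long-term hematopoietic stem cells sorted from mouse bone marrow, 3 from animals given saline and 3 from animals given carnosine. Per the labels' protocols, total RNA was purified with a column kit, samples passed a minimum RNA integrity number of 7.0, poly-A RNA was selected, and stranded paired-end libraries were sequenced on an Illumina NovaSeq. The submitters' processing notes name CASAVA 1.8, HISAT2, StringTie and edgeR with the mouse build GRCm38, and give no order, option or version for the last 3 of these tools. The strand setting used in counting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical copies (Hspa1a and Hspa1b, the hemoglobin pairs, histone genes, immunoglobulin V segments) could therefore be split between copies, and a gene and its antisense partner may share reads. The dose of carnosine, its duration, and the age, sex and number of mice are not given in the sources used here.

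Per the file headers, the authors deposited 1 raw count and 1 FPKM value per gene and library for 55487 genes. The count values were whole numbers with different totals per library, and were used as deposited. The deposited FPKM values were checked against the counts: dividing the count by the FPKM and the library's total gave a whole-number length, within 0.05, for 95.4% to 96.4% of values with over 20 counts, according to the library. All rows had a gene name, and 55141 identifiers were found in GENCODE M21, from which transcript GC content was taken. Gene lengths were those given by count, FPKM and total, as the median over the libraries.

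Totals ranged from 10304539 to 13251332 counts per library. A gene with 3 counts in a library, the upper limit that a count of 0 allows, corresponded to 0.226 to 0.291 CPM (counts scaled to library size). Such limits, and the exact 95% intervals given for ratios of small counts, cover counting error only, since the reads carry no molecular identifiers.

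Counts were scaled by the trimmed mean of M-values (TMM; factors 0.998 to 1.003) and filtered with filterByExpr on the group, which kept 15298 genes. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. The adjusted p-values given for genes are from this test, log2 fold changes are carnosine against saline with their standard errors (SE), and levels are CPM on the TMM scale as mean ± SD. Numbers in the labels do not say that a saline and a carnosine sample share a mouse, litter or day, so no block was fitted.

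Gene lists, 48 in all, were fixed before the data were examined. Of these, 47 had at least 5 members among the genes kept and were tested with camera (limma 3.58.1) on log-CPM with its preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 47 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation p can rise even where the estimate is under 0.01. For interferon-stimulated genes the estimate was -0.008, with an unadjusted camera p of 0.000351 against 5.47e-21 with the preset. A list's members past the gene test were counted over all genes tested and adjusted over the list alone. Adjusted p-values given for lists are from camera with the preset correlation unless an estimated correlation is named.

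The genes named were chosen by a rule written before the data were examined. It took, in each direction, the 12 genes with the largest log2 fold change among genes past the threshold whose groups did not overlap, with an average log2 CPM of at least 1, leaving out predicted genes and pseudogenes. To these it added up to 4 members with the smallest p in each list, the measured members of the sorting gate, histidine and carnosine, and sex-linked lists, and the 5 most abundant members of a list of another cell type. All 12 genes with the largest rise were immunoglobulin V segments, so the 12 largest rises outside immunoglobulin segments were added after their values were seen. Other genes named outside the rule are marked as chosen after their values were seen.

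The tests were run on simulated counts drawn from the libraries' own means and sizes. Known changes were given to 200 of 15298 genes, and a shift of 0.3 to a list of 30 others. In the simulation edgeR recovered 39.4% of genes changed by a log2 fold of 0.5, 77.6% at 1 and 92.5% at 2, and 8.75% of its calls were false. Camera gave p = 0.897 for a simulated list with no shift and p = 1.11e-20 for a list shifted by 0.3, against p = 0.000448 with an estimated correlation.

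Alternatives were DESeq2 1.42.0, limma-voom, other scalings (relative log expression, upper quartile, library totals only), no filter and a filter of 1 CPM in 3 samples, other thresholds, a replicate block, limma-trend on FPKM with pseudocounts of 1 and 0.1, and leaving out each library in turn. Immunoglobulin segments left out, and a correction for gene length and GC content, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out.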

Results

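Long-term hematopoietic stem cells (LT-HSCs), the bone marrow cells that sustain all blood lineages, were profiled by bulk RNA sequencing in unirradiated wild-type mice. They had been sorted as lineage-negative cells with Sca-1 and c-Kit and without Flk2 and CD34 on the surface. The design held 3 libraries from saline-treated mice and 3 from mice given carnosine, a dipeptide of beta-alanine and histidine that buffers protons and traps reactive carbonyls. The saline libraries held 10386171, 10304539 and 13210166 counts, and the carnosine libraries 12108727, 10442112 and 13251332. The first principal component took 48.2% of the variance and separated the groups.

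The comparison asks what carnosine changes in LT-HSC gene expression without irradiation. The labels do not say that the libraries of a group come from separate mice, so the p-values may describe technical spread only. In LT-HSCs from carnosine-treated mice, the lists of immediate early, interferon-stimulated and cholesterol synthesis genes were lower, and those of DNA replication, mitosis and respiratory complexes III to V were higher. Other lists, among them multipotent progenitor and neutrophil granule genes (lower) and erythroid genes (higher), were called with the preset correlation only (adjusted p = 0.068, 0.0928 and 0.068 with an estimated correlation). The progenitor and neutrophil lists share Mpo and Ctsg. Most antibody V segments, which belong to B lineage cells, rose. Of 15298 genes tested, 1455 rose and 1283 fell, most by a modest amount, with a median absolute log2 fold change of 0.32.

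Immediate early genes encode transcription factors and phosphatases switched on within minutes of a stimulus, including the handling of tissue. Of 29 tested, 21 fell and 6 rose, and 21 and 7 did when adjusted over the list alone (median log2 fold change -0.37, camera adjusted p = 2.89e-07). The AP-1 subunit Fosb (ENSMUSG00000003545, GRCm38 chromosome 7, 19302696 to 19310051) fell from 6157 ± 136 CPM (SD, n = 3) to 2774 ± 48.9 CPM (SD, n = 3), a log2 fold change of -1.15 (SE 0.02, edgeR adjusted p = 1.52e-07). Its dimer partner Jun and its paralog Fos fell by 0.90 and 0.80 on the log2 scale. Another AP-1 subunit, Fosl2, went the other way, from 278 ± 2.54 CPM to 612 ± 6.33 CPM (SD, n = 3). Together the list's genes took 3.89% of counts in saline and 2.66% in carnosine. The list named for quiescence and CDK inhibitors shares some of these genes and was not called (camera adjusted p = 0.369). In it 4 rose and 7 fell, 6 and 8 adjusted over the list alone, with the growth-restraining factors Klf6 (-0.63), Klf4 (-0.76), Egr1 (-0.60) and Btg2 (-0.58) among the falls.

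Hspa1b and Hspa1a are inducible chaperones of the Hsp70 family that refold proteins after heat or other stress. Among genes past the threshold whose groups did not overlap, with an average log2 CPM of at least 1, they had the largest falls. Predicted genes and pseudogenes were left out of that ranking. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) dropped from 85.5 ± 2.85 CPM to 9.25 ± 1.21 CPM (SD, n = 3), 9.25-fold lower in carnosine (edgeR adjusted p = 1.75e-06). Its near-identical neighbour Hspa1a fell from 32.6 to 4.98 CPM, and reads could be split between them. The co-chaperone Dnajb1 (-0.55) also fell, whereas Hspa9 (+0.31), a chaperone of the mitochondrial matrix, rose. The 29 heat shock and chaperone genes therefore split, with 8 up and 9 down (10 and 12 adjusted over the list alone), and the list was not called (camera adjusted p = 0.278). NF-kB and TNF response genes, which drive inflammatory signalling, fell as a list (median -0.24, camera adjusted p = 0.000343, and adjusted p = 0.068 with an estimated correlation). Of 30, 10 fell and 1 rose, 12 and 3 adjusted over the list alone. The feedback inhibitor Nfkbia (-0.33) and the chemokines Ccl3 (-0.54) and Cxcl2 (-0.53) were among the falls.

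Interferon-stimulated genes, the antiviral program induced by interferon receptors, gave the smallest list p in the comparison (median -0.50, camera adjusted p = 2.57e-19). Of 45 members 33 fell and 0 rose, and 41 fell and 1 rose when adjusted over the list alone. Oas2 (ENSMUSG00000032690, chromosome 5, 120730333 to 120749853), which makes the messenger that activates RNase L, fell from 169 ± 3.81 CPM to 63.0 ± 8.80 CPM (SD, n = 3; edgeR adjusted p = 7.78e-05). Stat2, the transducer of type I interferon signals, fell from 63.3 to 35.8 CPM. Oasl2 (-0.67) and the ADP-ribosyltransferase Parp14 (-0.51) fell as well, and Ifi213, a DNA-sensor family member, fell by 1.54 on the log2 scale.

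**Figure D1:**
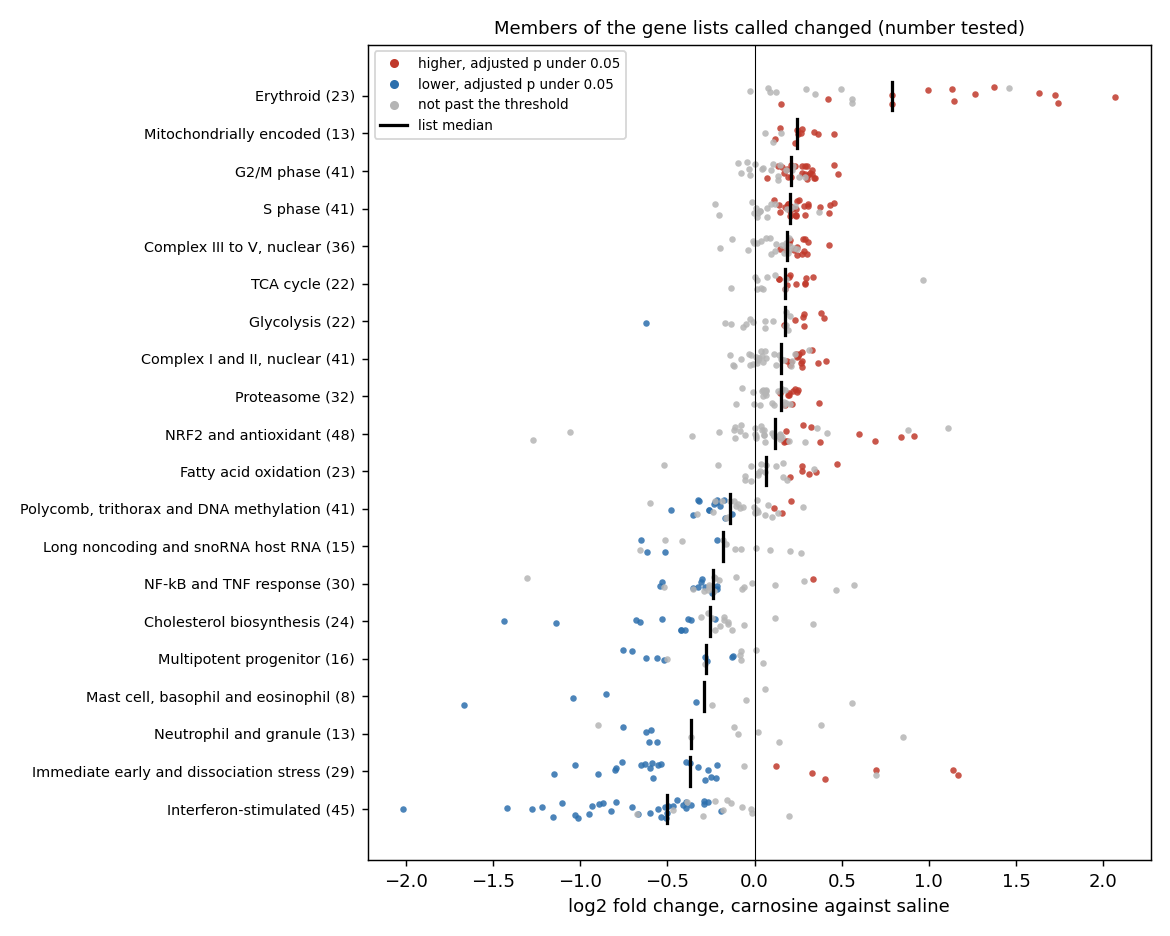
Log2 fold changes, carnosine against saline, of every tested member of the 20 gene lists called changed, with 3 libraries per group. Each point is a gene, red or blue where it passed the gene test upward or downward and grey where it did not, and black bars are list medians, from -0.50 for interferon-stimulated genes to 0.79 for erythroid genes.

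Of 41 S phase genes 24 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 5.17e-08). They included the primase-bound polymerase Pola1 (+0.46), the nucleotide reductase subunit Rrm1 (+0.43) and the helicase subunits Mcm7 (+0.31) and Mcm3 (+0.25). Of 41 G2/M genes 23 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 5.17e-08). Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), which untangles sister chromatids, rose from 672 ± 3.12 CPM to 829 ± 7.82 CPM (SD, n = 3; edgeR adjusted p = 6.95e-05), and cyclin Ccna2 rose by 0.48. RNA of histone genes made in S phase mostly lacks the poly-A tail selected for here, so that list cannot decide on replication. Its genes were not called (28 tested, 3 up and 1 down, 0 and 0 adjusted over the list alone, camera adjusted p = 0.119). Nor were MYC targets and ribosome biogenesis genes (38 tested, 7 up and 3 down, 9 and 4 adjusted over the list alone, camera adjusted p = 0.441), although the nucleolar protein Ncl rose by 0.19. Cytosolic ribosomal protein genes stayed near 0 (78 tested, median 0.04, 9 up and 2 down, the same counts adjusted over the list alone, camera adjusted p = 0.291).

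Repair lists were not called. Among 39 double-strand break repair genes 6 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.211), with Brca2 (+0.40), which loads the recombinase, up and the scaffold Mdc1 (-0.28) down. Excision and mismatch repair genes split as 4 up and 3 down of 37 (4 and 3 adjusted over the list alone, camera adjusted p = 0.291). Of 33 p53 targets 4 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.332); the cytokine Gdf15 (-1.09) and the death-promoting Bbc3 (-0.91) fell, and the kinase Plk2 (+0.55) rose. Apoptosis regulators were balanced, with 2 up and 3 down of 29 (2 and 3 adjusted over the list alone, camera adjusted p = 0.989).

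Among mitochondrial lists the share of members that rose varied. Of 13 mitochondrially encoded genes 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 5.25e-06, and adjusted p = 0.249 with an estimated correlation), led by the complex I subunits mt-Nd1 (+0.36) and mt-Nd5 (+0.34). Nuclear genes of complexes III to V followed, with 14 of 36 up and 0 down (17 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 1.09e-05). The catalytic ATP synthase subunit Atp5b rose from 847 ± 22.7 CPM to 1035 ± 14.4 CPM (SD, n = 3; edgeR adjusted p = 0.000356), with its partner Atp5a1 (+0.28) and the Rieske protein Uqcrfs1 (+0.28). Nuclear genes of complexes I and II gave 14 up and 0 down of 41 (16 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.000165, and adjusted p = 0.068 with an estimated correlation), among them Sdha (+0.26). The TCA cycle gave 11 up and 0 down of 22 (14 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.000117, and adjusted p = 0.0949 with an estimated correlation), with citrate synthase Cs (+0.34) and the pyruvate dehydrogenase subunit Pdha1 (+0.29). Mitochondrial ribosome genes were not called (42 tested, 3 up and 0 down, 0 and 0 adjusted over the list alone, camera adjusted p = 0.17).

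Fatty acid oxidation and glycolysis lists were called higher with the preset correlation only, and the cholesterol list lower with the preset and the estimated correlation. Fatty acid oxidation genes gave 6 up and 0 down of 23 (6 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.0268, and adjusted p = 0.133 with an estimated correlation), with Cpt1a (+0.47), the gatekeeper of mitochondrial fatty acid import. Their median was 0.12 without saline replicate 1, 0.10 without carnosine replicate 1 and 0.11 without carnosine replicate 2. That call was lost without saline replicate 3 and without carnosine replicate 3 (camera adjusted p = 0.0543 in both). Glycolysis genes gave 7 up and 1 down of 22 (9 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0356, and adjusted p = 0.145 with an estimated correlation), including Ldha (+0.28) and Pgk1 (+0.40), and lost the call without carnosine replicate 1 (camera adjusted p = 0.0501) or 3 (0.0862). Of 24 cholesterol genes 11 fell and 0 rose (12 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 2.77e-07). The sterol sensor Insig1 fell from 63.7 ± 4.47 CPM to 39.8 ± 1.86 CPM (SD, n = 3; edgeR adjusted p = 0.000807), and the synthesis enzyme Msmo1 (-1.14) fell too. Hypoxia response genes were not called, with 3 up and 4 down of 21 (3 and 5 adjusted over the list alone, camera adjusted p = 0.989).

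Carnosine is a carbonyl trap and antioxidant. NRF2 and antioxidant genes gave 12 up and 0 down of 48 (12 and 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.00158, and adjusted p = 0.068 with an estimated correlation). The peroxidase of the secretory pathway Prdx4 rose from 34.4 ± 2.38 CPM to 55.6 ± 1.62 CPM (SD, n = 3; edgeR adjusted p = 0.000585), and thioredoxin Txn1 (+0.37) and its reductase Txnrd1 (+0.18) rose. Carbonyl and aldehyde detoxification genes were not called (22 tested, 4 up and 0 down, the same counts adjusted over the list alone, camera adjusted p = 0.0625), although the aldehyde dehydrogenase Aldh1a1 rose by 0.62. That list was called higher without a filter on low counts (camera adjusted p = 0.0107), without saline replicate 1 (0.0413), and, chosen after seeing the data, with immunoglobulin segments left out (0.0435) or with the length and GC correction (0.0304), and by fry (0.00137). Ferroptosis genes were not called (19 tested, 1 up and 0 down, the same adjusted over the list alone, camera adjusted p = 0.268); the glutathione-degrading enzyme Chac1 was the 1 that rose, from 10 counts in all saline libraries to 80 in all carnosine libraries. Histidine and carnosine handling genes split, with 4 up and 4 down of 17 (5 and 5 adjusted over the list alone, camera adjusted p = 0.735). The amino acid transporter Slc7a5 (+0.42) and the taurine transporter Slc6a6 (+0.31) rose. The carnosine synthase Carns1 (-0.43, edgeR adjusted p = 0.0353) fell, but the call was lost when 1 library was left out (adjusted p up to 0.108). The cytosolic dipeptidase Cndp2, which cleaves carnosine, was 49.0 CPM in saline and 55.0 CPM in carnosine (edgeR adjusted p = 0.0626), and the serum carnosinase Cndp1 and peptide transporter Slc15a1 had 0 counts in every library.

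Protein turnover was mixed. Proteasome genes gave 11 up and 0 down of 32 (14 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.000126, and adjusted p = 0.068 with an estimated correlation), with the core subunit Psma2 (+0.37) and the regulatory-particle subunit Psmd1 (+0.25). Unfolded protein and integrated stress response genes were not called, with 5 up and 8 down of 34 (5 and 10 adjusted over the list alone, camera adjusted p = 0.444), the calcium-binding chaperone Calr falling by 0.23. Autophagy and lysosome genes gave 1 up and 5 down of 37 (2 and 7 adjusted over the list alone, camera adjusted p = 0.268).

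Polycomb, trithorax and DNA methylation genes gave 3 up and 14 down of 41 (4 and 17 adjusted over the list alone, median -0.14, camera adjusted p = 0.00492, and adjusted p = 0.0742 with an estimated correlation). After a correction for gene length and GC content, chosen after seeing the data, that median was -0.08 and the call was lost (camera adjusted p = 0.0922). The histone demethylase Kdm6b (-0.48), the oxidase Tet3 (-0.26) and the methyltransferase Kmt2c (-0.36) fell, while the maintenance DNA methyltransferase Dnmt1 (+0.21) rose. Long noncoding and snoRNA host RNAs gave 0 up and 4 down of 15 (0 and 5 adjusted over the list alone, median -0.18, camera adjusted p = 0.0104, and adjusted p = 0.107 with an estimated correlation), including the nuclear RNA Malat1 (-0.62) and the imprinted Kcnq1ot1 (-0.65).

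Stem cell identity genes did not move as a list (35 tested, median 0.00, 4 up and 3 down, the same counts adjusted over the list alone, camera adjusted p = 0.989). The niche ligand Angpt1 (+0.29) rose, and the costimulatory receptor Cd27 (-0.34) and the transcription factor Runx1 (-0.39) fell. Multipotent progenitor genes fell, with 0 up and 9 down of 16 (0 and 10 adjusted over the list alone, median -0.28, camera adjusted p = 3.09e-05, and adjusted p = 0.068 with an estimated correlation). The peroxidase Mpo fell from 516 ± 4.71 CPM to 306 ± 5.54 CPM (SD, n = 3; edgeR adjusted p = 2.96e-06), and the myeloid factor Cebpa (-0.52) and the lymphoid polymerase Dntt (-0.27) fell. Mpo and Ctsg also belong to the neutrophil and granule list, so the calls of those lists are not independent. The progenitor genes Cd34, Cd48 and Il7r did not pass (edgeR adjusted p = 0.887, 0.516 and 0.291). None of the 7 sorting gate genes was called (0 and 0 adjusted over the list alone, camera adjusted p = 0.658). Flt3 RNA, which encodes Flk2, was 818 CPM in saline and 775 CPM in carnosine (edgeR adjusted p = 0.0503). It was called lower under each of the 3 other scalings, with the filter of 1 CPM in 3 samples (edgeR adjusted p = 0.0479) and with limma-voom (adjusted p = 0.0325). Cd34 RNA was 857 CPM in saline and 861 CPM in carnosine. Both RNAs were read although the gate selects cells without either protein on the surface. The name LT-HSC is that of the labels. How many progenitors the sort held was not tested, so the changes reported may include those of progenitors.

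Signals from the niche gave no called list. Wnt and Notch genes split into 7 up and 4 down of 29 (7 and 5 adjusted over the list alone, camera adjusted p = 0.232), with the Notch ligand Jag2 (+0.81), the Wnt receptors Fzd4 (+1.37) and Lrp5 (+0.43) and the Notch target Nrarp (+0.73) up. TGF-beta and BMP genes gave 1 up and 5 down of 23 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0856), with the BMP targets Id1 (-0.57) and Id3 (-0.61) down. Niche adhesion and homing genes gave 5 up and 0 down of 30 (6 and 0 adjusted over the list alone, camera adjusted p = 0.203), including the phagocytosis signal Cd47 (+0.15).

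**Figure D2:**
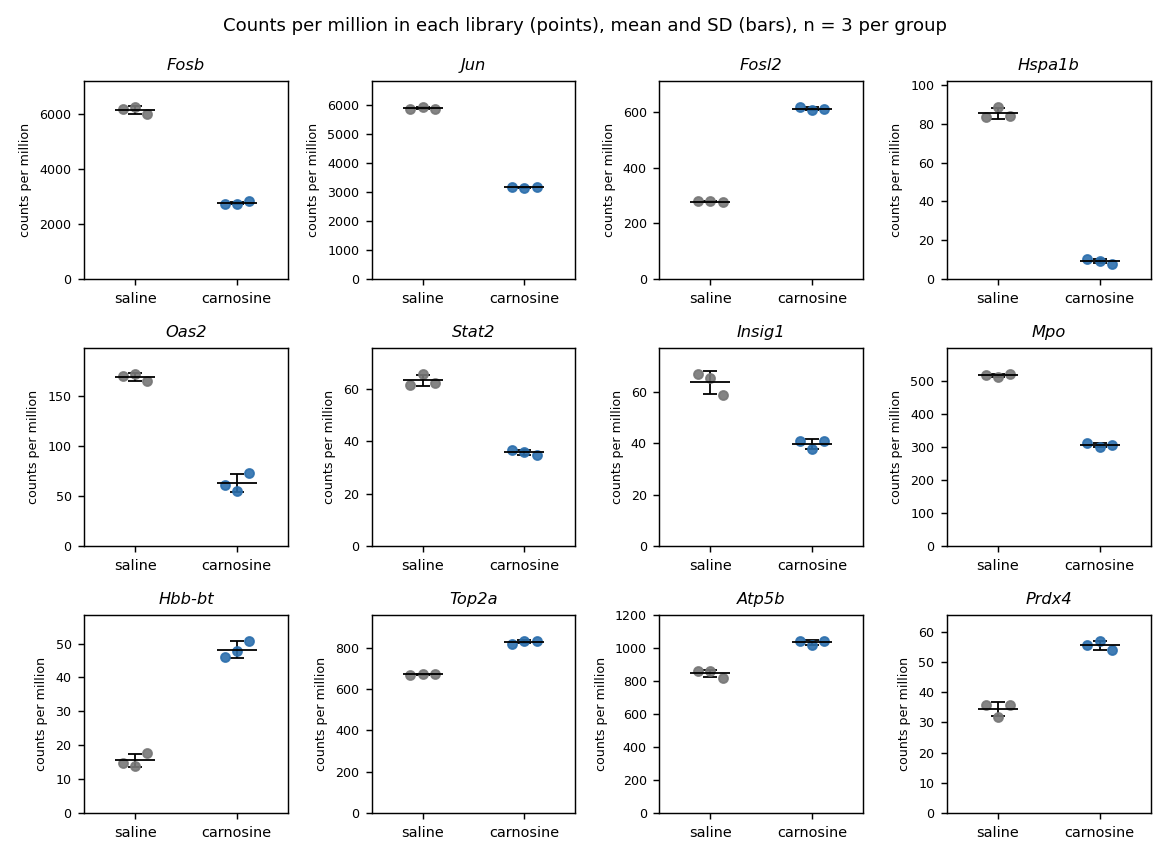
CPM of 12 genes in the 3 saline and 3 carnosine libraries, on axes that start at 0. Points are libraries and black bars the mean with SD; Fosb ran near 6157 CPM in saline and 2774 CPM in carnosine, and the groups did not overlap for any of the 12.

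Some lists of mature lineages were called, in both directions and with the preset correlation only. Erythroid genes rose, with 13 up and 0 down of 23 (16 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 3.97e-08, and adjusted p = 0.068 with an estimated correlation). The beta-globin Hbb-bt rose from 15.5 ± 2.01 CPM to 48.2 ± 2.49 CPM (SD, n = 3; edgeR adjusted p = 6.5e-05), and its near-identical copy Hbb-bs, Hba-a1 and the anion exchanger Slc4a1 rose too. Neutrophil and granule genes fell, with 0 up and 5 down of 13 (0 and 6 adjusted over the list alone, median -0.36, camera adjusted p = 0.00272, and adjusted p = 0.0928 with an estimated correlation), among them the cytokine receptor Csf3r (-0.61) and elastase Elane (-0.62). Their median was -0.10 without carnosine replicate 1, -0.22 without carnosine replicate 3 and -0.23 without a filter on low counts, which each tested more members, and the call was kept. Mast cell, basophil and eosinophil genes gave 0 up and 4 down of 8 (0 and 4 adjusted over the list alone, median -0.29, camera adjusted p = 0.0188, and adjusted p = 0.206 with an estimated correlation), with the basophil proteases Prss34 (-1.67) and Mcpt8 (-1.04). That list lost its call without saline replicate 3 (camera adjusted p = 0.0723), and its median was -0.57 without carnosine replicate 1, -0.68 without carnosine replicate 3 and -0.52 without a filter on low counts. Monocyte, macrophage and dendritic cell genes were not called (22 tested, 1 up and 2 down, 1 and 6 adjusted over the list alone, camera adjusted p = 0.0625), although the growth factor receptor Csf1r fell by 1.12. That list was called lower without saline replicate 2 (camera adjusted p = 0.0304), without carnosine replicate 2 (0.0443) and, chosen after seeing the data, with the length and GC correction (0.0474).

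The remaining lineage lists were not called. Megakaryocyte and platelet genes gave 3 up and 1 down of 19 (the same adjusted over the list alone, camera adjusted p = 0.444), including the myosin kinase Mylk (+0.49). T and NK cell genes gave 1 up and 2 down of 18 (the same adjusted over the list alone, camera adjusted p = 0.444). Endothelial genes gave 2 up and 1 down of 18 (the same adjusted over the list alone, camera adjusted p = 0.444), with the scavenger receptor Stab2 (+0.95). Stromal, osteoblast and adipocyte genes gave 1 up and 0 down of 11 (the same adjusted over the list alone, camera adjusted p = 0.0901), the 1 being the chemokine Cxcl12 (+1.01), and were called higher without carnosine replicate 3 (camera adjusted p = 0.0474). B cell and plasma cell genes gave 5 up and 6 down of 19 (5 and 7 adjusted over the list alone, camera adjusted p = 0.441). Y-linked genes were read in both groups, with Ddx3y at 95.2 CPM in saline and 90.9 CPM in carnosine, and Xist had 20 counts in the saline and 27 in the carnosine libraries. The sex-linked list had under 5 tested members and no list test.

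Antibody gene segments had the 12 largest rises among genes past the threshold whose groups did not overlap, with an average log2 CPM of at least 1. Predicted genes and pseudogenes were left out. Of 155 V segments tested, 123 rose and 5 fell, with a median log2 fold change of 1.90, and that median was the same with the 15 segments at 3 or fewer counts in a group set to their bound. Igkv1-88 had 0 counts in saline and was at least 99.5-fold higher in carnosine, against 3 counts over the group. Ighv8-12 had 1 count in saline and 605 in carnosine, a ratio of 575 (exact 95% interval 103 to 22749). The kappa constant gene Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966) rose from 276 ± 5.75 CPM to 901 ± 14.5 CPM (SD, n = 3; edgeR adjusted p = 5.82e-08). The antibody-joining chain Jchain rose 3.35-fold (edgeR adjusted p = 0.00649), with a wide spread between replicates. It was 157, 89.7 and 161 CPM in saline and 296, 536 and 537 CPM in carnosine. The mu constant gene Ighm fell by 0.29. Segments together took 0.194% of counts in saline and 0.584% in carnosine. Outside immunoglobulin genes and within the same limits, the largest rises, chosen after their values were seen, included the chemokine Cx3cl1 (+2.10), the zinc finger gene Zfp180 (+1.93), the calcium channel Cacna1h (+1.81), the urokinase receptor Plaur (+1.57) and the cytokine Il10 (+1.53).

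**Figure D3:**
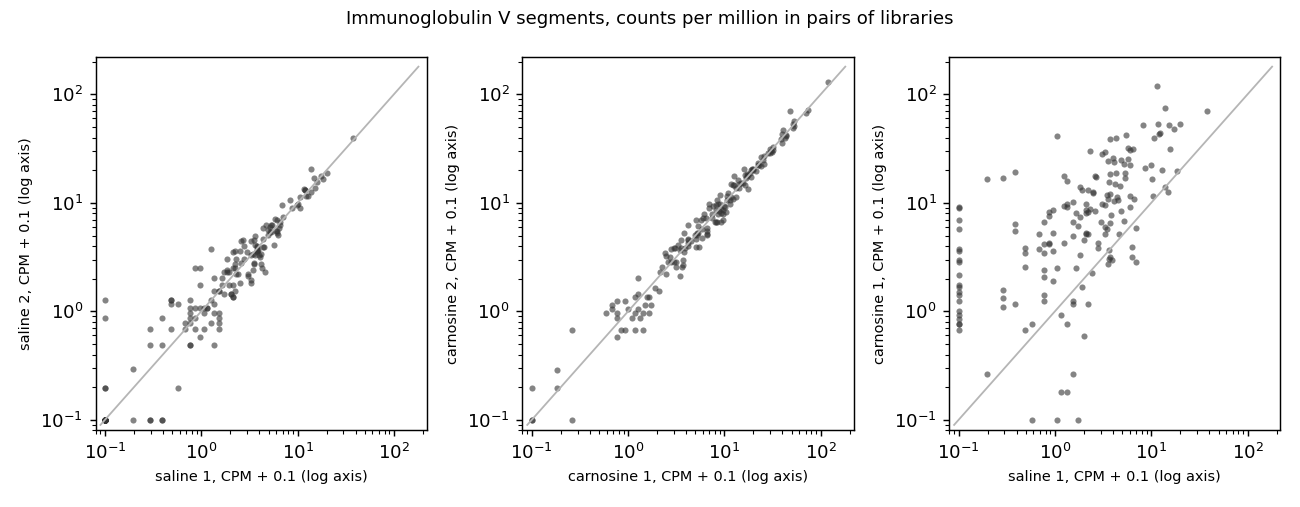
CPM of immunoglobulin V segments in pairs of libraries, on log axes after adding 0.1, each point a segment and the line equality. Segments of saline 1 and 2, and of carnosine 1 and 2, lie along the line, while carnosine 1 lies mostly above saline 1, where 123 of 155 tested segments rose.

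Over all genes, 2738 of 15298 (17.9%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 190 of them up and 123 down by a log2 fold of at least 1. The count fell whichever library was left out. It was 1848, 1753 and 1822 without saline replicates 1, 2 and 3, and 1769, 1892 and 1797 without carnosine replicates 1, 2 and 3. In the same order, genes lower fell from 1283 to 849, 801, 823, 837, 883 and 842. Genes higher fell from 1455 to 999, 952, 999, 932, 1009 and 955. The groups did not overlap for 38.7% of tested genes, against 10% expected by chance. Of the 47 lists tested, 11 were higher, 9 lower and 27 not called. With an estimated correlation 6 calls held: the interferon-stimulated, S phase, G2/M, cholesterol, immediate early and complex III to V lists. The directional test of fry, which asks whether a list's genes move on balance one way, passed for 39 lists and its mixed test, which asks whether they change in either direction, for 46, and neither compares a list with other genes. Median, mean and test differed in sign for 6 lists, none of them called: B cell and plasma cell, unfolded protein, histidine and carnosine, apoptosis, hypoxia and HSC identity. The labels do not say that the replicates come from separate mice, so the p-values measure the spread between these samples only, which may be technical.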

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

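The count of 2738 changed genes (1455 higher, 1283 lower) stayed within 1.5 times its value under the other scalings, the filter of 1 CPM in 3 samples and limma-voom (2691 to 2756). Scaling moved the share of calls that were higher from 53.1% to as low as 47.9%. DESeq2 called 1834, of which 813 were lower. FPKM without a filter gave 1599 (882 higher, 717 lower), a log2 fold limit of 1 gave 313 (190 and 123), and an unadjusted p under 0.05 gave 5027 (2572 and 2455). Leaving out 1 library, which leaves fewer samples, gave 1753 to 1892 changed, 932 to 1009 higher and 801 to 883 lower genes. The 20 called lists became 18 to 21 on leaving out 1 library (10 to 12 higher, 8 to 10 lower). Without a filter 18 lists were higher, from 11, adding carbonyl (camera adjusted p = 0.0107), double-strand break repair (0.0209), cytosolic ribosomal (0.0192), mitochondrial ribosome (0.00912), niche (0.0160), stromal (0.00679) and histone genes (0.00679). An estimated correlation left 6 lists (3 higher, 3 lower), and fry called 39 (23 and 16), since it asks a different question. Fry put the B cell and plasma cell list upward (adjusted p = 0.00940) against its median of -0.35. Across the other scalings and filters, the replicate block, limma-voom, DESeq2 and each library left out, 167 of 199 called genes named kept their call. The other 32 lost it, 31 of them with 1 library left out, and 0 changed sign. Named genes were not followed under the other thresholds or on FPKM, where only the number of calls was taken. Chosen after seeing the data, leaving immunoglobulin segments out gave 2541 changed genes and 21 lists, and a correction for gene length and GC content gave 21 lists, 19 of them shared, with the Polycomb list lost as its median moved from -0.14 to -0.08 (camera adjusted p = 0.0922). Other causes of these changes were not tested. A gene changed by a log2 fold of 0.5 was recovered in 39.4% of simulated cases. The simulation changed a far smaller share of genes than was called here, so its adjusted threshold was stricter. That rate therefore cannot be carried over to these data, where called genes had a median absolute log2 fold change of 0.32. How many small changes were missed was not tested, and some may be.

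A block on the replicate number gave 1756 changed genes (946 higher, 810 lower), 1705 of them shared, and the same 20 lists. The numbers do not pair the samples: libraries with the same number had deviations correlated at -0.050, -0.069 and 0.019, and 1 of 3 saline libraries best matched its own number.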

Other observations

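The tests of the V segments and their matched genes, plasma cell markers, TEC genes and immediate early genes, and the receptor count without its most abundant genes, were chosen after the results were seen, unlike the splits, the receptor ratio and the test over all lower genes. Antibody classes moved unequally. IgA heavy chain RNA (Igha) rose from 591 ± 2.89 CPM to 2250 ± 45.8 CPM (SD, n = 3), and the gamma chains Ighg1 (+3.09), Ighg2b (+1.67) and Ighg2c (+0.62) rose, while the mu chain Ighm (-0.29), which marks B cells before class switching, fell. The inflammation-amplifying receptor Trem1 (+1.21) and the RNA-destabilizing protein Zfp36l1 (+1.17) rose. The V segment Igkv4-63 fell, with 66 counts in saline and 3 in carnosine. The genes of this part, apart from Ighm, Slamf1 and the listed plasma cell markers, were chosen after their values were seen. Stem cell marker Procr was 36.0 CPM in saline and 33.7 CPM in carnosine (edgeR adjusted p = 0.43), and Slamf1 was 4.28 and 3.64 CPM.

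Counts by class of RNA, which had no test of their own, are given beside the 1455 genes that rose and 1283 that fell of all 15298 tested. Of 1445 processed pseudogenes, copies of spliced RNA, 157 rose and 15 fell (median 0.13). Among 246 antisense genes 0 rose and 13 fell, and of 388 genes of the annotation's TEC class, which holds unspliced clusters with poly-A features, 1 rose and 67 fell (median -0.47). Ribosomal RNA took 0.0498% of counts in saline and 0.0887% in carnosine.

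The immunoglobulin V segments differed between the groups by the index of dispersion of their shares in pairs of libraries (1 for counting noise alone), set beside the 20 other genes nearest to each segment in count, since the index grows with the count. Within a group the mean index was 1.33 to 1.58 over 6 pairs, against 2.04 to 3.19 for the matched genes and 5.23 to 6.40 for all other genes, but the medians were closer (0.955 to 1.66 against 1.43 to 1.72). Between groups it was 20.6 to 26.8 over 9 pairs, against 3.84 to 4.62 for the matched genes and 13.4 to 15.8 for all other genes. That argues against more antibody-secreting cells of the same repertoire (20.6), and is consistent with the 3 libraries of a group coming from one shared pool of cells or one mouse (1.58), in which case the p-values would describe technical spread. More antibody-secreting cells, of any repertoire, stay open, although the lineage-negative gate would remove such cells. The 11 tested markers of 12 listed had a median of 0.57 (camera p = 0.0128, 0.0594 with an estimated correlation), and 4 are held by another list. Of the 11, 5 rose and 1 fell. The 1 that fell was Sdc1, from 37.7 ± 2.30 CPM to 27.8 ± 2.32 CPM (SD, n = 3; edgeR adjusted p = 0.0115). Xbp1 (61.0 and 65.2 CPM) and Txndc5 (112 and 110 CPM) did not pass.

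Intergenic repeat genes were higher in saline. The 4 repeat genes Gm10800, Gm10801, Gm10722 and Gm21738 took 0.0317% of counts in saline and 0.00488% in carnosine. Genomic DNA carried into the saline libraries may contribute. A set of 1490 olfactory and vomeronasal receptor genes, taken as silent in blood cells, had a saline to carnosine ratio of 2.24 (95% interval 2.05 to 2.45). It was 5.82 (5.03 to 6.76) without the 8 genes with at least 20 counts. The remaining genes held 1179 of 1586 counts in saline but only 214 of 748 in carnosine. Those 8 genes may thus be expressed, and the first ratio includes them. Spread evenly by gene length, the rate from all 1490 genes gave a median 0.463% of the TEC fall. By it, 0% of 1283 lower genes had at least 50% of their fall accounted for. Carried-over DNA need not be read evenly along the genome, so this test cannot decide whether it contributed to either.

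Immediate early genes were lower in carnosine. A weaker response to tissue handling, alike for every immediate early gene, would lower them together, but 22.2% of changed members rose. That share was known when the test was written, so no conclusion is drawn from it. A weaker response that differs between genes stays open. Another time between death and lysis in the carnosine samples cannot be told apart from the treatment, because handling times are not given in the sources used here and would be shared by a group (list median -0.37). An effect of carnosine on these genes also stays open and untested.

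The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2738 genes and the highest other 6, and for lists 20 and 8, with 1 split each as large as the real one.

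Some genes differed between replicates of 1 group. Of 9007 genes with a mean above 16 CPM, 251 in saline and 229 in carnosine had a library over 1.5-fold from the other 2, which lay within 1.2-fold, and 80 did in both groups (6.38 by chance). The Polycomb gene Pcgf5 was 50.2, 152 and 143 CPM in saline and 49.4, 45.5 and 45.4 CPM in carnosine, and actin Actb, apart in both groups, was 1783, 1165 and 1796 CPM in saline and 1248, 1905 and 1955 CPM in carnosine.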
